A study of Mus musculus with 6 samples.

How the data were processed

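Spinal cord tissue of wild-type mice was taken 3 days after a T10 contusion, from 3 animals given PBS and 3 given syringin at 50 mg/kg a day. Per the labels' protocols, RNA was isolated with TRIzol, and stranded libraries were made from polyadenylated RNA with a TruSeq kit and sequenced. The submitters' processing notes name HISAT2 and StringTie and the builds GRCm38 and mm10, with no versions. The authors deposited 1 table of 37475 genes with an estimated count and an FPKM value per gene and library. The estimated counts as deposited are whole numbers, so rounding them changed nothing, and the FPKM values are as the authors deposited them, scaled by transcript length and library size. Whether counting used strand, and how reads shared between genes were assigned, is not given in the sources used here. Of the genes, 1880 had 0 counts in every library and 245 shared a symbol with another gene. The table's coordinates were compared with a GRCm38 annotation (GENCODE M21): of 34804 shared gene IDs, 34803 lay on the same chromosome, 717 had the same start and 30210 the same span length, so the coordinates come from another build or annotation than that one.

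The library totals were 65.6 to 78.8 (in units of 1e+06 counts). Among 20868 genes with 1 transcript, counts of 4, 8, 12 and 16 were 1.5, 1.34, 1.30 and 1.18 times as frequent as the mean of their neighbours, so 1 fragment may add about 4 counts. Divided by 4, the totals would be 16.4 to 19.7 in the same unit. The mitochondrial share was 4.63% to 7.00% and the 10 most abundant genes took 6.40% to 8.61% of the counts. No pair of libraries held identical counts, and libraries of 1 group differed by more than counting noise (chi-square over its degrees of freedom 31.3 to 147.3).

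Samples were grouped by the treatment in their labels. The test, its threshold, the gene lists, the rule for named genes and the first set of other settings were fixed before the data were examined. Counts were scaled by the trimmed mean of M-values (TMM, factors 0.9655 to 1.0292), filtered with filterByExpr (minimum count 10, minimum total 15), which left 22114 genes, and fitted with edgeR 4.0.16's quasi-likelihood model with robust estimation, in R 4.3.3, with treatment as the only term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05; p-values are two-sided. The common biological coefficient of variation was 24.9%. Standard errors are the absolute log2 fold change over the square root of F. CPM are counts per 1e+06 after TMM scaling. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01, over the lists with 5 or more tested members, with camera at an estimated correlation and fry beside it. The rule for named genes took the 15 largest rises and the 15 largest falls among called genes with a mean of 1 CPM or more, non-overlapping groups and a name that is not a clone or predicted name. It also took the 4 members with the smallest p of each called list and of each list with 3 or more called members, and 16 genes fixed in advance, from Il1b to Cldn5. Some genes that the rule takes are not reported here.

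The settings fixed then were RLE, upper-quartile and no composition factors, DESeq2 1.42.0, limma-voom, edgeR without robust estimation, other filters on low counts, a fold threshold of 2, the replicate number as a block, scaling without haemoglobin and mitochondrial genes, and each library left out in turn. Settings chosen after the data were seen were counts divided by 4, limma on log2(FPKM + 0.1), a correction of each library for transcript length and GC content, the mean of the sensory ganglion list per library as a covariate, and DESeq2 and limma-voom without PBS library 3. Terms of the GO and KEGG columns of the deposited table, with 15 to 500 tested genes, were tested for enrichment with a one-sided hypergeometric test, also chosen after the data were seen, against the 17126 and 7131 tested genes with a term. Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and figures.

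The edgeR test was tested on simulated counts of the comparison of syringin with PBS, over 21511 genes of which 189 were changed. It recovered 8.5%, 43.8% and 71.2% of genes changed by log2 0.58, 1 and 1.5, with 6 false among 86 calls. With 4 counts per fragment, over 21443 genes, it recovered 14.1%, 40% and 77.8%, with 3 false among 87 calls, and without planted changes it called 1 and 0 genes. In these simulations most changes of log2 0.58 and of log2 1 were missed. With so few changed genes, the adjusted threshold was stricter there than in the data, where 1108 genes were called. Of those, 37 higher and 245 lower genes changed by a factor of 2 or more. A planted gene list was recovered with no other list called. Each gene was drawn independently there, so false list calls from correlation between genes could not show. A planted slope on transcript length of -0.3 was measured as -0.302 before and -0.012 after correction. The enrichment test called 0 terms in a random draw of genes, which holds no correlation between genes either.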

Results

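RNA sequencing was used to measure gene expression in the spinal cord of wild-type mice 3 days after a contusion, a blunt impact on the cord at the T10 level. After the injury the mice received daily intraperitoneal injections of phosphate-buffered saline (PBS), the vehicle, or of syringin at 50 mg/kg. Syringin is a plant phenylpropanoid glucoside, the glucoside of sinapyl alcohol. Each group held 3 biological replicates, and each library was made from the polyadenylated RNA of cord tissue. The deposited gene counts of the PBS libraries summed to 74495190, 66771594 and 67580815, and those of the syringin libraries to 78843034, 65579117 and 70505235. Small counts piled up at multiples of 4: the value 4 occurred 1.5 times as often as the mean of 3 and 5. If 1 fragment adds about 4 counts, the counting error is larger than these totals imply. Uninjured cord was not analysed here, so all values compare 2 groups of injured animals. Gene coordinates are given as in the deposited table. The submitters' processing notes name the build GRCm38 (mm10), but only 717 of 34804 gene IDs shared with a GRCm38 annotation have the same start there, so the build of the printed coordinates is uncertain.

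The first principal component of the 22114 genes tested held 32.1% of the variance and the second 24.0%. On the first, the PBS libraries scored -50.0, -25.4 and -33.9 and the syringin libraries -0.2, 72.9 and 36.7. On the second, PBS library 1 and syringin libraries 1 and 3 scored 27.4, 56.8 and 19.8, and PBS libraries 2 and 3 and syringin library 2 scored -38.8, -41.5 and -23.8. Over the 500 most variable genes the first component, with 33.9% of the variance, did not separate the treatments: the PBS libraries scored -26.4, 13.8 and 14.3 and the syringin libraries -27.6, 35.9 and -10.0. The second, with 21.9%, did, at -8.5, -24.9 and -19.4 against 10.3, 24.1 and 18.4. Markers of sensory ganglion neurons, cells that lie outside the cord, divided the libraries as the second component of all genes and the first of the 500 did. The sodium channel gene Scn10a had 3429 counts in PBS library 1, 3558 in syringin library 1 and 818 in syringin library 3, against 15, 0 and 0 counts in PBS libraries 2 and 3 and syringin library 2. A count of 0 allows up to 3 fragments, from counting error only. Xist, the non-coding RNA of the inactive X chromosome, had between 50012 and 65754 counts in every library (log2 fold change 0.01 ± 0.09, adjusted p = 0.947). The deposited table does not list the Y chromosome genes Ddx3y, Kdm5d, Uty and Eif2s3y.

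**Figure D1:**
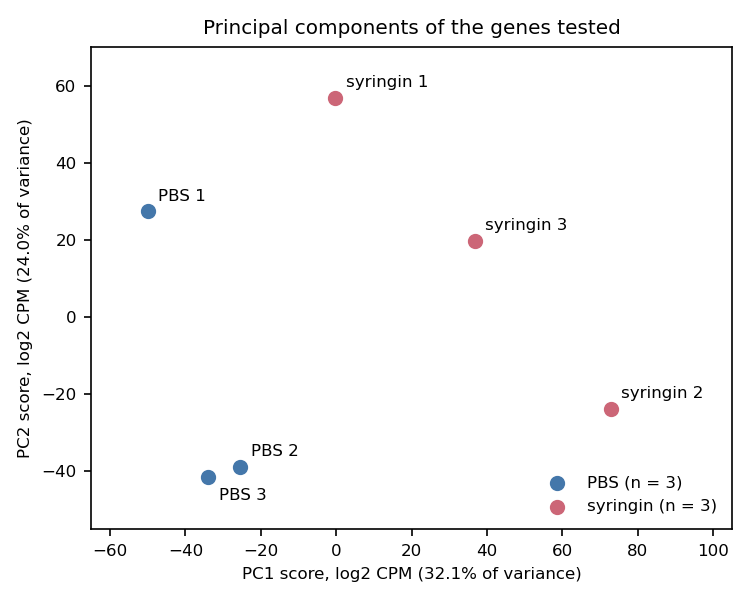
Scores of the 6 libraries on the first (x axis) and second (y axis) principal components of log2 CPM (counts per 1e+06 counts) of the 22114 genes tested, 1 point per library, coloured by treatment. The 3 PBS libraries lie between -50.0 and -25.4 on the first component and the 3 syringin libraries between -0.2 and 72.9.

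The comparison of syringin with PBS asked how gene expression in the injured cord differed with the treatment. By camera with a preset correlation of 0.01 between genes, lists of neurons, of excitatory and inhibitory transmission and of astrocytes were lower in the syringin group, and lists of infiltrating monocytes and macrophages, of NF-kB inflammatory cytokines and of the cell cycle were higher. None of these 6 calls held with the correlation estimated from the data (adjusted p = 0.444, 0.21, 0.21, 0.21, 0.368 and 0.464). That version of camera also uses fewer degrees of freedom, which makes a call harder to reach at any correlation. The glycine transporter gene Slc6a5 of inhibitory neurons fell from 169 ± 9.46 to 74.4 ± 7.32 CPM (mean ± SD, n = 3 in each group), and the complement receptor gene C5ar1 of myeloid cells rose from 41.1 ± 1.29 to 77.2 ± 5.55 CPM. In all, 1108 of 22114 genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 359 of them higher and 749 lower in the syringin group. The median absolute log2 fold change was 0.60 among the higher and 0.85 among the lower genes, and 37 higher and 245 lower genes changed by a factor of 2 or more. All 1108 genes had the 3 values of 1 group above the 3 of the other, as did 30% of all genes tested, where chance gives 10%. After correction of each library for transcript length and GC content, chosen after the data were seen, 670 genes were higher and 609 lower, so the share of higher genes was 52.4% in place of 32.4%. The number of changed genes depended on single libraries. Without PBS library 1, 2 or 3, edgeR called 263, 184 and 0 genes, and without syringin library 1, 2 or 3 it called 1944, 436 and 251. Without PBS library 3, 3449 genes had an unadjusted p under 0.05 in edgeR, and limma-voom called 0 and DESeq2 1466 genes, so no gene described below as changed passed edgeR's adjusted threshold without that library. The sign of all 1108 fold changes was the same in each of these fits. With the 3 values of 1 group above the 3 of the other, leaving out a library could hardly reverse a sign. The shared sign is therefore no evidence for the calls. With the mean of the sensory ganglion markers as a covariate, chosen after their values were seen, 2589 genes passed, among them all 1108. DESeq2 on all 6 libraries called 3191 genes, 1401 higher and 1790 lower.

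Of the 61 gene lists fixed for cell types and pathways, 22 were higher and 12 lower in the syringin group by camera with the preset correlation, at an adjusted p of 0.05. With the correlation estimated from the data none was called, the smallest adjusted p being 0.210, and 8 lists had an unadjusted p under 0.05. That version of camera also uses only the few residual degrees of freedom of 6 libraries, which raises p at any correlation. For the alternative macrophage state list the estimated correlation was -0.045, below the preset value. Its unadjusted camera p still went from 0.000598 to 0.0215. The loss of the calls therefore does not show that correlation between genes undid them. The test fry, which asks whether a list's genes move 1 way on balance, called 15. It called excitatory and inhibitory transmission, astrocytes and infiltrating monocytes and macrophages (adjusted p = 0.0127 for each). It did not call neurons, NF-kB inflammatory cytokines or the cell cycle (adjusted p = 0.0883, 0.0548 and 0.125). Fry also called AMPK and sirtuin lower (adjusted p = 0.0164), a list that camera did not call (adjusted p = 0.609). Each list below is given with the members that passed over all genes tested and, where it differs, with the count adjusted over the list alone. Several lists share members, so their results are not independent. The shift of a list is the mean log2 difference between the groups over its members minus that over all other genes; it is given for called lists where leaving out 1 library moved it by over 1.5 times, and the list mean of a library is relative to all 6 libraries. All fold changes are log2, syringin minus PBS, ± the standard error, with n = 3 in each group.

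**Figure D2:**
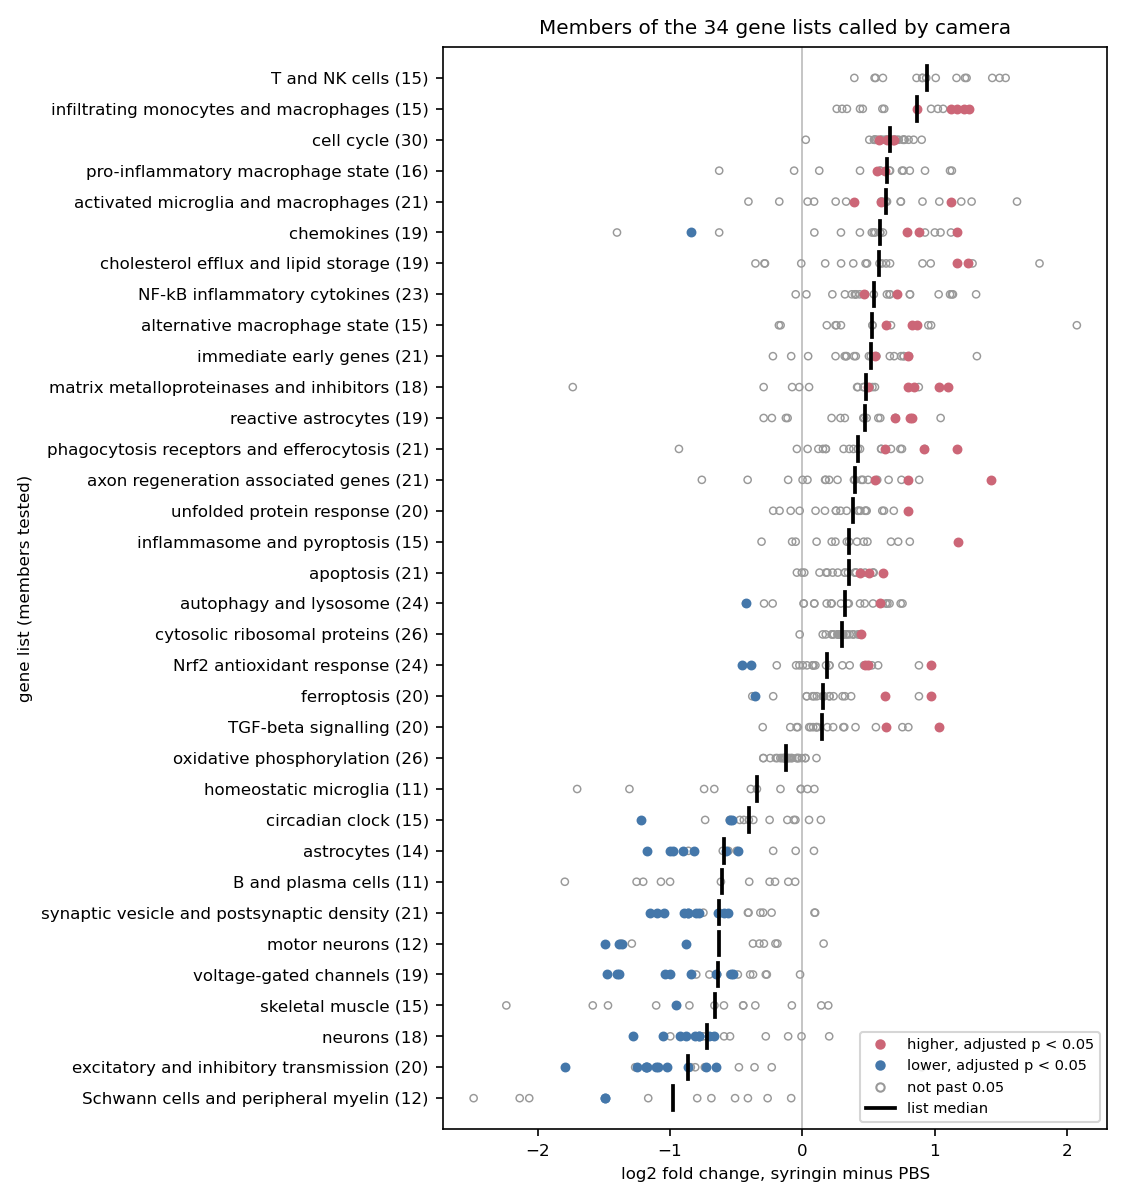
Log2 fold change, syringin minus PBS, of each tested member (x axis) of the 34 gene lists called by camera with a preset correlation (y axis, with the number of members tested). Filled points passed an adjusted p of 0.05 in edgeR (red higher, blue lower), open points did not, and the bars are list medians, which run from -0.98 for Schwann cells and peripheral myelin to 0.94 for T and NK cells.

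Of 20 genes of excitatory and inhibitory transmission, 11 fell, none rose, and 9 did not pass (18 lower adjusted over the list alone; median -0.86). For the excitatory and inhibitory transmission list, camera gave adjusted p = 2.61e-10, and adjusted p = 0.21 with an estimated correlation. Members with the smallest p included genes of inhibition: the glycine transporter Slc6a5 (ENSMUSG00000039728, chromosome 7, 49559894 to 49613604) changed by -1.18 ± 0.10 (adjusted p = 0.0101) and the vesicular inhibitory amino acid transporter Slc32a1 by -1.17 ± 0.13. Among voltage-gated channels 9 of 19 fell and none rose (10 lower adjusted over the list alone; median -0.64). Camera on voltage-gated channels gave adjusted p = 1.44e-08, and adjusted p = 0.425 with an estimated correlation. The potassium channel genes Kcna2 (ENSMUSG00000040724, chromosome 3, 107008462 to 107022321), Kcnc1 and Kcnd2 changed by -1.48 ± 0.14, -1.38 ± 0.13 and -1.0 ± 0.11, and the sodium channel gene Scn1a by -1.40 ± 0.15. Of the synaptic vesicle and postsynaptic density list, 11 of 21 fell and none rose (17 lower adjusted over the list alone), with Rab3a at -1.04 ± 0.15, Cplx1 at -1.09 ± 0.16 and Rims1 at -1.15 ± 0.18. For the synaptic vesicle and postsynaptic density list, camera gave adjusted p = 1.21e-08, and adjusted p = 0.425 with an estimated correlation. Among general neuronal markers 9 of 18 fell and none rose (14 lower adjusted over the list alone). Camera on neurons gave adjusted p = 6.92e-07, and adjusted p = 0.444 with an estimated correlation. The neurofilament gene Nefh went from 490 ± 130 to 202 ± 15.3 CPM (-1.28 ± 0.19, adjusted p = 0.0188), and Thy1, Syn2 and Map2 changed by -0.67 ± 0.10, -0.81 ± 0.12 and -0.70 ± 0.11. Of 12 motor neuron markers 4 fell and none rose (6 lower adjusted over the list alone; median -0.63). For motor neurons, camera gave adjusted p = 0.000437, and adjusted p = 0.425 with an estimated correlation. The shift of the motor neurons list was -0.69, but -0.35 without PBS library 1, 1 of the libraries with ganglion transcripts, and -0.40 without syringin library 2; its list mean was 1.05, -0.08 and 0.16 in the PBS and 0.07, -0.98 and -0.22 in the syringin libraries. The 4 fallen genes were the cholinergic Slc5a7 (-1.39 ± 0.13), Chat (-1.49 ± 0.20), Slc18a3 (-1.36 ± 0.23) and Ache (-0.88 ± 0.18); Slc18a3 lies within Chat on the same strand, so their counts may share reads. The neuronal nuclear marker Rbfox3 had a value of -1.0 ± 0.25 and missed the threshold (adjusted p = 0.0601). Markers of infiltrating macrophages were higher in the same libraries (list median 0.87), and the mean of the sensory ganglion markers, relative to the 6 libraries, was 2.85, -2.00 and -2.31 in the PBS and 2.79, -2.90 and 1.57 in the syringin libraries.

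**Figure D3:**
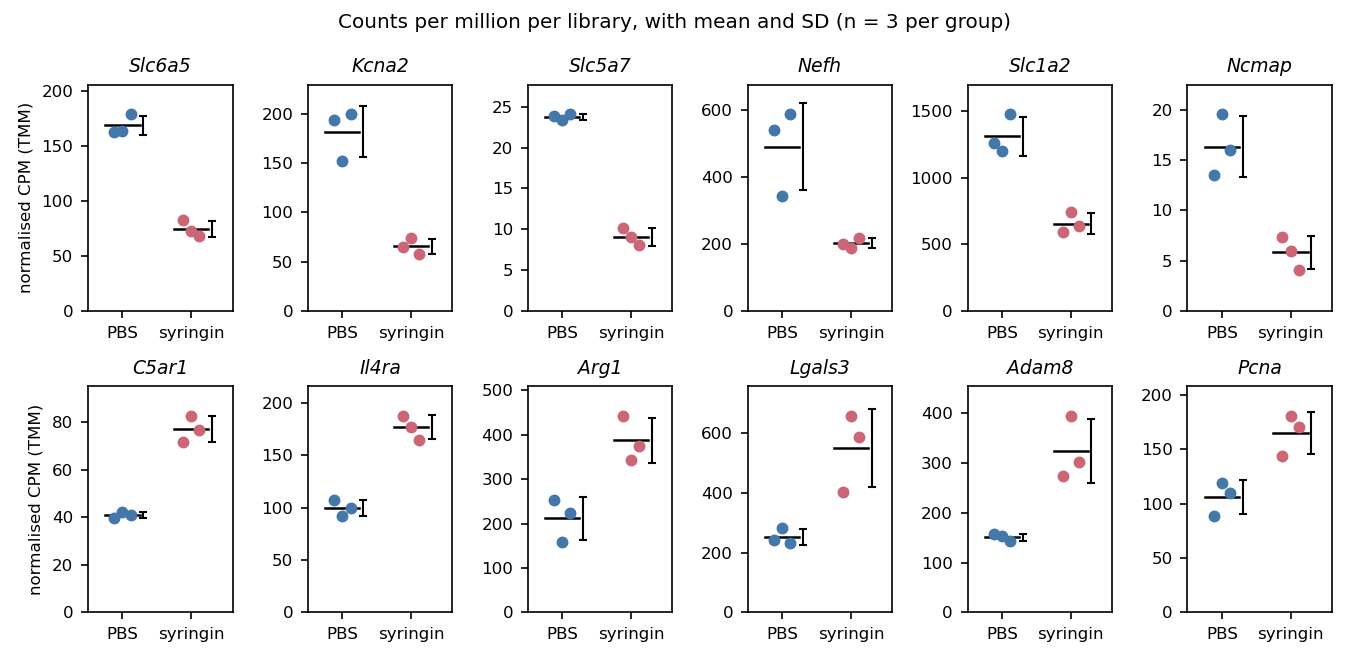
Normalised CPM (y axes, each from 0) of 12 named genes in each library, with blue points for PBS and red points for syringin, horizontal lines at group means and bars of 1 SD (n = 3). In each panel the 3 values of 1 group lie above the 3 of the other, as for Slc6a5, at 163 to 179 CPM with PBS and 68.4 to 82.5 CPM with syringin.

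Glial genes did not move as 1 group. Of 14 markers of resting astrocytes, 7 fell and none rose (8 lower adjusted over the list alone; median -0.59). Camera on astrocytes gave adjusted p = 1.49e-05, and adjusted p = 0.21 with an estimated correlation. The glutamate transporter Slc1a2 fell from 1310 ± 146 to 656 ± 78.2 CPM (-1.0 ± 0.13, adjusted p = 0.0137), the gap junction gene Gjb6 changed by -1.17 ± 0.19, Gpc5 by -0.98 ± 0.17 and Mlc1 by -0.57 ± 0.10. In the reactive astrocyte list 3 of 19 members rose and none fell (8 higher adjusted over the list alone; median 0.47). For reactive astrocytes, camera gave adjusted p = 0.00062, and adjusted p = 0.368 with an estimated correlation. The risen genes were Emp1 (0.81 ± 0.09), Cd44 (0.83 ± 0.11) and the intermediate filament gene Vim (0.70 ± 0.16), genes that macrophages and other cells also express, and Tm4sf1 had a value of 0.70 ± 0.17 (adjusted p = 0.0585). Gfap, the main astrocyte filament, did not pass, at 5000 ± 593 and 4090 ± 681 CPM (-0.29 ± 0.16, adjusted p = 0.326). The homeostatic microglia list was lower without any member passing over all genes (2 lower adjusted over the list alone; median -0.34); P2ry12 and Gpr34 had values of -0.74 ± 0.21 and -0.67 ± 0.19, Siglech -1.70 ± 0.61 and Slc2a5 -1.31 ± 0.45. Camera on homeostatic microglia gave adjusted p = 0.0359, and adjusted p = 0.68 with an estimated correlation. That call was lost without PBS library 3 (adjusted p = 0.0995), without syringin library 1 (0.295) and with the ganglion covariate (0.11). Homeostatic microglia had a shift of -0.48, and -0.24 without syringin library 1. No member of the oligodendrocyte and myelin list passed (18 tested, median 0.11, camera adjusted p = 0.0843), Mbp being at 10900 ± 590 and 10800 ± 1930 CPM (-0.01 ± 0.16). The oligodendrocyte progenitor list had no member past the threshold (4 higher adjusted over the list alone; median 0.23, camera adjusted p = 0.0524). Endothelial markers held 1 risen gene, Pecam1, of 18 (median 0.23, camera adjusted p = 0.0524), and Cldn5 of the blood-brain barrier had a value of 0.19 ± 0.13 (adjusted p = 0.441). With the ganglion covariate the progenitor and endothelial lists were called higher (adjusted p = 0.0156 and 0.0283).

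Genes of macrophages and inflammation were higher in the syringin group, while neuronal and astrocyte markers were lower in the same libraries (list medians -0.72 and -0.59). All 15 markers of infiltrating monocytes and macrophages had positive fold changes and 5 rose (7 higher adjusted over the list alone; median 0.87). For infiltrating monocytes and macrophages, camera gave adjusted p = 2.74e-06, and adjusted p = 0.21 with an estimated correlation. The coagulation factor gene F10 rose by 1.26 ± 0.15, the lectin Clec4d by 1.12 ± 0.14, thrombospondin Thbs1 by 1.22 ± 0.26 and the arginase Arg1 from 212 ± 48.5 to 387 ± 51.2 CPM (0.87 ± 0.18, adjusted p = 0.0395). Of the list of activated microglia and macrophages, 3 of 21 rose (9 higher adjusted over the list alone; median 0.63): the galectin Lgals3 by 1.13 ± 0.18, Cd63 by 0.59 ± 0.10 and Csf1 by 0.39 ± 0.08. Camera on activated microglia and macrophages gave adjusted p = 0.000263, and adjusted p = 0.578 with an estimated correlation. The mean of the activated list was -0.47, -0.19 and -0.14 in the PBS and -0.30, 0.77 and 0.33 in the syringin libraries, so syringin library 1 lay below PBS libraries 2 and 3. The shift of the activated microglia and macrophages list was 0.59, 0.89 without syringin library 1 and 0.33 without syringin library 2. Cd68 had a value of 1.03 ± 0.27 (adjusted p = 0.0666) and Aif1, the general microglia and macrophage marker, 0.09 ± 0.25. Phagocytosis receptors held 3 risen genes of 21 (8 higher adjusted over the list alone), the Fc receptor Fcgr1 at 0.62 ± 0.08 and the scavenger receptors Msr1 at 0.92 ± 0.13 and Cd36 at 1.17 ± 0.25. For the phagocytosis receptors and efferocytosis list, camera gave adjusted p = 9.02e-05, and adjusted p = 0.481 with an estimated correlation. Over phagocytosis receptors and efferocytosis the shift was 0.45, and 0.26 without syringin library 2. The pro-inflammatory macrophage list held 2 risen genes of 16, Fcgr1 and Irf5 (7 higher adjusted over the list alone), and the alternative macrophage list 3 of 15, Arg1, the interleukin-4 receptor Il4ra (0.83 ± 0.09) and Tgfb1 (0.64 ± 0.14). Camera on the pro-inflammatory macrophage state list gave adjusted p = 4.81e-05, and adjusted p = 0.346 with an estimated correlation. For the alternative macrophage state list, camera gave adjusted p = 0.00152, and adjusted p = 0.21 with an estimated correlation. Lists of opposed macrophage states were thus both higher, and whether they differed was not tested. Of 23 NF-kB and cytokine genes the inhibitor Tnfaip3 (0.71 ± 0.16) and the adaptor Myd88 (0.46 ± 0.11) rose (8 higher adjusted over the list alone; median 0.54). Camera on NF-kB inflammatory cytokines gave adjusted p = 1.11e-06, and adjusted p = 0.368 with an estimated correlation. The cytokines Tnf, Il6 and Il1b were low, at 1.32 ± 0.279, 0.924 ± 0.397 and 4.98 ± 1.17 CPM with PBS and 2.89 ± 0.934, 2 ± 0.89 and 8.74 ± 4.14 CPM with syringin, and missed the threshold (adjusted p = 0.084, 0.167 and 0.2), as did Nos2 (0.66 ± 0.20, adjusted p = 0.0993) and the mannose receptor Mrc1 (0.19 ± 0.30).

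Among chemokines Ccl3, Cxcl1 and Ccl2 rose, by 0.79 ± 0.14, 1.17 ± 0.22 and 0.88 ± 0.19, and the neuronal chemokine Cx3cl1 fell by 0.84 (19 tested; 10 higher and 1 lower adjusted over the list alone). For chemokines, camera gave adjusted p = 0.000794, and adjusted p = 0.21 with an estimated correlation. In the complement list the receptors C5ar1 (0.91 ± 0.09, adjusted p = 0.0101) and C3ar1 (0.82 ± 0.17) and properdin, Cfp (0.84 ± 0.19), rose, Serping1 had a value of -0.55 ± 0.14, and the list of 16 was not called (4 higher and 3 lower adjusted over the list alone; camera adjusted p = 0.433). The inflammasome list held 1 risen gene of 15, Mefv (1.18 ± 0.26) (2 higher adjusted over the list alone), and its call was lost without syringin library 2 (adjusted p = 0.0514). Camera on the inflammasome and pyroptosis list gave adjusted p = 0.0125, and adjusted p = 0.461 with an estimated correlation. Of 26 interferon response genes 1, Cmpk2, fell and none rose (median -0.07, camera adjusted p = 0.5). All 15 T and NK cell markers had positive fold changes, but none passed alone (median 0.94); Trbc2 was at 1.47 ± 0.214 and 2.75 ± 0.596 CPM, and Cd3d, Cd8a and Cd2 were lower still with PBS, between 0.263 and 0.719 CPM. For T and NK cells, camera gave adjusted p = 0.000148, and adjusted p = 0.444 with an estimated correlation. The shift of the T and NK cells list was 1.10, but 0.66 without PBS library 2; its list mean was -0.30, -1.31 and 0.05 in the PBS and -0.02, 0.84 and 0.74 in the syringin libraries, so syringin library 1 lay below PBS library 3. All 11 B and plasma cell markers had negative fold changes and none passed (median -0.61), with Ighm at -1.07 ± 0.31. Camera on B and plasma cells gave adjusted p = 0.012, and adjusted p = 0.425 with an estimated correlation. Dendritic cell and antigen presentation genes were not called (15 tested, none past the threshold, median 0.59, camera adjusted p = 0.101) but were called higher with the ganglion covariate (adjusted p = 0.0269). In the neutrophil list of 16, Mmp8 rose and the granule enzyme Mpo fell (-1.99 ± 0.34), with 1 higher and 2 lower adjusted over the list alone, and the list was not called (camera adjusted p = 0.146).

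Genes of the cell cycle were higher in the syringin group. All 30 had positive fold changes and 4 rose, or 28 adjusted over the list alone (median 0.66). For the cell cycle list, camera gave adjusted p = 4.6e-10, and adjusted p = 0.464 with an estimated correlation. That correlation was 0.854, so the counts of members are not counts of independent genes, and fry did not call the list (adjusted p = 0.125). The cell cycle mean was -0.62, -0.13 and -0.20 in the PBS and -0.07, 0.61 and 0.41 in the syringin libraries. The replication genes Pcna (0.64 ± 0.13), Mcm5 (0.70 ± 0.15) and Mcm2 (0.68 ± 0.15) and the chromatin protein Hmgb2 (0.58 ± 0.12) passed; a transcript lies antisense to Pcna, and the counting strand is not given in the sources used here. Cytosolic ribosomal protein genes were higher by a small and even amount (median 0.30, 25 of 26 positive, 1 past the threshold and 22 adjusted over the list alone). Camera on cytosolic ribosomal proteins gave adjusted p = 3.44e-09, and adjusted p = 0.425 with an estimated correlation. Rps2 passed (0.44 ± 0.09), and Rplp0 and Rpl18 had values of 0.42 ± 0.10 and 0.39 ± 0.09; these genes have many processed pseudogenes that can share their reads. Of 21 apoptosis genes 3 rose (8 higher adjusted over the list alone), among them the pro-apoptotic Bak1 (0.44 ± 0.09) and the anti-apoptotic Mcl1 (0.51 ± 0.11). For the apoptosis list, camera gave adjusted p = 7.34e-05, and adjusted p = 0.368 with an estimated correlation. In the unfolded protein response list Atf3 alone of 20 rose (0.80 ± 0.17; 6 higher adjusted over the list alone). Camera on the unfolded protein response list gave adjusted p = 0.000586, and adjusted p = 0.425 with an estimated correlation. Jun (0.55 ± 0.09) and Atf3 were also the risen members of 21 immediate early genes (5 higher adjusted over the list alone), a call lost without syringin library 3 (adjusted p = 0.0651). For immediate early genes, camera gave adjusted p = 0.000732, and adjusted p = 0.643 with an estimated correlation. Immediate early genes had a shift of 0.48, and 0.18 without syringin library 3. With the growth factor Gdnf (1.43 ± 0.31), Jun and Atf3 were the 3 risen of 21 axon regeneration genes. Camera on axon regeneration associated genes gave adjusted p = 0.0011, and adjusted p = 0.444 with an estimated correlation. Junb and Zfp36 had values of 0.69 ± 0.18 and 0.76 ± 0.22, and Npy 0.46 ± 0.14. Heat shock proteins were not called (camera adjusted p = 0.15; 1 of 15 fell, Hspa4l).

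Proteases of the matrix were higher: of 18 metalloproteinases and inhibitors 5 rose (9 higher and 1 lower adjusted over the list alone; median 0.48). For matrix metalloproteinases and inhibitors, camera gave adjusted p = 0.000817, and adjusted p = 0.21 with an estimated correlation. Adam8 went from 151 ± 7.34 to 323 ± 63.6 CPM (1.10 ± 0.14, adjusted p = 0.0129), the urokinase receptor Plaur changed by 0.85 ± 0.15 and Adamts4 by 0.50 ± 0.10. Of 20 TGF-beta genes 2 rose, among them Tgfb1 (4 higher adjusted over the list alone), and the list's call was lost without syringin library 2 (adjusted p = 0.0743). Camera on the TGF-beta signalling list gave adjusted p = 0.0122, and adjusted p = 0.368 with an estimated correlation. Among 21 fibrotic scar genes Tnc and Tgfbi rose (camera adjusted p = 0.362), and Col1a1 had a value of -0.13 ± 0.43 (adjusted p = 0.896). Not called were fibroblasts and meninges (17 tested, none past the threshold and 2 lower adjusted over the list alone, camera adjusted p = 0.105), chondroitin sulphate proteoglycans (16 tested, none past the threshold, but 3 higher and 3 lower adjusted over the list alone, camera adjusted p = 0.814) and axon guidance and myelin inhibitors (1 of 22 fell, Slit2, camera adjusted p = 0.382). Pericytes and smooth muscle (camera adjusted p = 0.515) and ependymal cells (camera adjusted p = 0.97) held no changed member.

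Of 19 genes of cholesterol efflux and lipid storage, the lipid droplet gene Plin2 rose from 167 ± 34 to 399 ± 132 CPM (1.25 ± 0.25) and Cd36 also rose (3 higher adjusted over the list alone), while Nceh1 and Fabp5 had values of 0.48 ± 0.13 and 0.91 ± 0.31. For the cholesterol efflux and lipid storage list, camera gave adjusted p = 0.012, and adjusted p = 0.68 with an estimated correlation. That call was lost without PBS library 1 (adjusted p = 0.0582) and without syringin library 2 (0.129). Cholesterol efflux and lipid storage had a shift of 0.54, 0.84 without syringin library 1 and 0.24 without syringin library 2. In the autophagy and lysosome list of 24 the cathepsin Ctsl rose (0.59 ± 0.13) and the autophagy kinase Ulk1 fell (-0.43 ± 0.10) (8 higher and 2 lower adjusted over the list alone; without syringin library 2 the adjusted p was 0.0601). Camera on the autophagy and lysosome list gave adjusted p = 0.012, and adjusted p = 0.578 with an estimated correlation. For the autophagy and lysosome list the shift was 0.30, and 0.17 without syringin library 2. Of 24 Nrf2 antioxidant genes 3 rose and 2 fell (7 higher and 2 lower adjusted over the list alone; median 0.19). For the Nrf2 antioxidant response list, camera gave adjusted p = 0.012, and adjusted p = 0.425 with an estimated correlation. The pentose phosphate enzymes Taldo1 and Pgd rose by 0.47 ± 0.08 and 0.50 ± 0.10, and the ferritin light chain Ftl1, which has many pseudogenes, by 0.97 ± 0.22; the glutathione transferase Gstm1 and the superoxide dismutase Sod2 changed by -0.46 ± 0.08 and -0.39 ± 0.09. Haem oxygenase, Hmox1, was at 764 ± 240 CPM with PBS and 1410 ± 134 CPM with syringin and just missed the threshold (0.88 ± 0.21, adjusted p = 0.0544), and Nqo1, Gpx4 and Slc7a11 had values of 0.18 ± 0.13, 0.03 ± 0.08 and 0.08 ± 0.32. The ferroptosis list of 20 held the risen iron genes Steap3 (0.62 ± 0.14) and Ftl1 and the fallen transferrin receptor Tfrc (-0.36 ± 0.08) (4 higher and 1 lower adjusted over the list alone), and its call was lost without PBS library 3 (adjusted p = 0.0514) and without syringin library 3 (0.0643). Camera on the ferroptosis list gave adjusted p = 0.0314, and adjusted p = 0.368 with an estimated correlation.

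Oxidative phosphorylation genes were slightly lower with no member past the threshold (26 tested, median -0.12); Sdha had a value of -0.30 ± 0.08. For the oxidative phosphorylation list, camera gave adjusted p = 0.0164, and adjusted p = 0.602 with an estimated correlation. The call was lost without PBS library 1, syringin library 1 or syringin library 2 (adjusted p = 0.0703, 0.0614 and 0.0808). Oxidative phosphorylation genes had a shift of -0.05, and -0.03 without either PBS library 1 or syringin library 1. The glycolysis list was not called (camera adjusted p = 0.966), with a median of 0.05 and a mean of -0.03, yet 5 of its 20 genes changed, or 3 higher and 4 lower adjusted over the list alone. The changed genes were Eno2, Aldoc and Pfkm, which fell by 0.78, 0.90 and 0.55, Ldhb, which also fell, and Ldha, which rose (0.51 ± 0.11). Of 15 circadian clock genes 3 fell (6 lower adjusted over the list alone; median -0.40). Camera on the circadian clock list gave adjusted p = 0.000459, and adjusted p = 0.21 with an estimated correlation. The fallen clock genes were the output factors Hlf (from 39 ± 4.13 to 16.8 ± 0.309 CPM, -1.21 ± 0.11, adjusted p = 0.0101) and Tef (-0.55 ± 0.09) and the repressor Nr1d1 (-0.53 ± 0.11), and the time of day at which tissue was taken is not given in the sources used here. Other pathways were not called by camera: hypoxia response (1 of 18 rose, Ldha, or 3 adjusted over the list alone, camera adjusted p = 0.282), cholesterol biosynthesis (none of 21, 0.362), AMPK and sirtuin (Ppargc1a and Sirt3 of 17 fell, 0.609), glucocorticoid response (1 of 15 fell, Sult1a1, 0.909), xenobiotic response (none of 11, 2 higher adjusted over the list alone, 0.97), PI3K and Akt signalling (Pik3r5 rose and 1 fell of 22, 0.999) and mitochondrially encoded genes (none of 13, 0.18). Fry called AMPK and sirtuin lower (adjusted p = 0.0164), though its median was -0.01. The xenobiotic list had a positive median of 0.07 and a negative mean of -0.28, the PI3K list a median of -0.03 and a mean of 0.01, and the ependymal list a negative median against an upward test.

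Markers of tissue next to the cord differed between libraries too. Of 12 genes of Schwann cells and peripheral myelin 2 fell (8 lower adjusted over the list alone; median -0.98). For Schwann cells and peripheral myelin, camera gave adjusted p = 0.000148, and adjusted p = 0.425 with an estimated correlation. Ncmap changed by -1.49 ± 0.24 and Drp2 by -1.49 ± 0.28, and the peripheral myelin genes Pmp22 and Pmp2 had values of -1.16 ± 0.29 and -2.06 ± 0.54. In the skeletal muscle list 1 of 15 fell, Pvalb (-0.95 ± 0.14), which inhibitory and sensory neurons also express; Acta1, Ckm and Myh7 had values of -1.47 ± 0.48, -2.24 ± 0.77 and -0.95 ± 0.33. Camera on the skeletal muscle list gave adjusted p = 0.00383, and adjusted p = 0.425 with an estimated correlation. The shift of the skeletal muscle list was -0.67, but -0.41 without PBS library 2; its list mean was 0.06, 0.86 and 0.17 in the PBS and -0.19, -0.57 and -0.34 in the syringin libraries. Ckm stood at 0.424, 1.35 and 0.161 CPM in the PBS libraries and did not pass (adjusted p = 0.133). The sensory ganglion list was not called (12 tested, none past the threshold, camera adjusted p = 0.5). Erythroid markers were not called (none of 12, 1 lower adjusted over the list alone, median -0.22, camera adjusted p = 0.138), nor were platelets (1 of 9 rose, Pf4, or 2 adjusted over the list alone, 0.758), bone and cartilage (1 of 10 fell, Ibsp, and 1 was also higher adjusted over the list alone, 0.3) and adipocytes (none of 6, 0.367). Mast cell markers had only 2 expressed members and were not tested.

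The largest rises among genes at 1 CPM or more included neighbouring kallikrein protease genes on chromosome 7, Klk9 (ENSMUSG00000047884, chromosome 7, 43441315 to 43446181), at 1.84 ± 0.31, and Klk8 (ENSMUSG00000064023, chromosome 7, 43447001 to 43453246), at 1.61 ± 0.30 and from 14.1 ± 5.25 to 43.2 ± 13.1 CPM; the transcript 2310002F09Rik overlaps both on the other strand. The AP-1 factor Fosl1 rose by 1.44 ± 0.31, the interleukin-7 receptor Il7r by 1.43 ± 0.21, the myeloid receptors Trem1 and Clec4n by 1.36 ± 0.28 and 1.22 ± 0.27, the stress cytokine Gdf15 by 1.28 ± 0.23, Serpinb2 by 1.27 ± 0.28, Mylk2 by 1.53 ± 0.30, Fcrlb by 1.26 ± 0.27 and Rasl11a by 1.24 ± 0.24. Among genes at this level the largest fall was that of Gnasas1 (ENSMUSG00000086537, chromosome 2, 174123024 to 174137229), at -2.78 ± 0.31, a transcript antisense to Gnas whose reads cannot be told from those of Gnas unless counting used strand. The dendritic protein Ddn changed by -2.70 ± 0.58, Lingo4 by -2.38 ± 0.41, the lens crystallin Crybb1 by -2.34 ± 0.40, the spectrin Sptbn5 by -2.08 ± 0.43 and the homeobox factor Lhx4 by -1.83 ± 0.25. Among ion channels, the glycine receptor Glra1 fell from 18.1 ± 1.93 to 5.22 ± 2.57 CPM (-1.79 ± 0.34), and the potassium channels Kcng4 (ENSMUSG00000045246, chromosome 8, 120350593 to 120362419) and Kcnj14 changed by -1.76 ± 0.32 and -1.90 ± 0.44. Cyp4f15, Myadml2 and Ankfn1 changed by -1.83 ± 0.38, -1.82 ± 0.33 and -1.72 ± 0.22, and the mitochondrial histidine transfer RNA mt-Th by -1.75 ± 0.34, which poly(A) selection captures poorly. The adjusted p of these genes lay between 0.0114 for Gnasas1 and 0.049 for Kcnj14. Genes that overlap a transcript on the opposite strand share the uncertainty of Gnasas1, because whether counting used strand is not given in the sources used here. Among the changed genes named here these are Klk8, Klk9, Fosl1, Thbs1, Ddn, Sptbn5, Rab3a, Scn1a, Syn2, Chat, Tef, Pcna, Myd88, Irf5, Bak1, Jun, Ccl3, Adam8, Adamts4, Ftl1 and Pfkm. Serpinb2 overlaps Serpinb10 on the same strand. Some members fall outside the naming rule and were named after their values were seen: Pecam1, Cmpk2, Mmp8, Tnc, Tgfbi, Slit2, Hspa4l, Ldhb, Ppargc1a, Sirt3, Sult1a1, Pik3r5, Pf4, Ibsp and Scn10a.

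Lists not called with all 6 libraries were called by camera when 1 library was left out. Without PBS library 1 these were sensory ganglion neurons and glucocorticoid response, higher (adjusted p = 0.0117 and 0.0372), and fibroblasts and meninges, lower (0.00249). Without PBS library 2, endothelial cells, oligodendrocyte progenitors and oligodendrocytes and myelin were called higher (adjusted p = 0.0224, 0.0373 and 0.0355). Without PBS library 3, dendritic cells, fibrotic scar, oligodendrocyte progenitors and oligodendrocytes were called higher (adjusted p = 0.0397, 0.0443, 0.0385 and 0.0397) and interferon response lower (0.0194). Without syringin library 1, dendritic cells, endothelial cells, hypoxia response, oligodendrocyte progenitors and oligodendrocytes were called higher (adjusted p = 0.000183, 0.00858, 0.0209, 0.00392 and 0.0292), and cholesterol biosynthesis and neutrophils lower (0.0186 and 0.0213). Without syringin library 2, oligodendrocytes and sensory ganglion neurons were called higher (adjusted p = 0.0299 and 0.0128) and fibroblasts and meninges lower (0.0129). Without syringin library 3, erythroid cells and mitochondrially encoded genes were called lower (adjusted p = 0.00199 and 3.45e-05). With the ganglion covariate, cholesterol biosynthesis was called lower (adjusted p = 0.00768).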

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

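The counts divided by 4, the FPKM values, the length and GC correction, the sensory ganglion covariate and the other tools without PBS library 3 were tests chosen only after the result was seen. The 1108 changed genes kept their sign wherever they were tested, in every alternative run. Their groups did not overlap, so this was largely fixed in advance and is no evidence for the calls. The count stayed within 1.5 times of 1108 under RLE (1111) and upper-quartile factors (1103), library totals only (1002), limma-voom (1052) and no robust estimation (1040). It also did so with no filter (1155), a CPM filter (1352), no haemoglobin and mitochondrial genes (1099), counts divided by 4 (1328) and the length and GC correction (1279, 943 of them shared). That correction moved the higher genes from 359 to 670, and limma on log2(FPKM + 0.1) gave 742 changed and 211 higher genes; the cause was not tested. DESeq2 called 3191 genes, 1401 higher and 1790 lower, and the cause was not tested. A fold of 2 or more, a stricter rule by construction, left 282 genes, 37 higher and 245 lower. With the ganglion covariate 2589 genes were called, 1153 higher and 1436 lower.

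The number of changed genes ranged from 0 without PBS replicate 3 to 1944 without syringin replicate 1, the higher from 0 to 813 and the lower from 0 to 1131. It was 263 without PBS replicate 1, 184 without PBS replicate 2, 436 without syringin replicate 2 and 251 without syringin replicate 3. Each of these fits has fewer samples; the cause of the higher count without syringin replicate 1 was not tested. Without PBS replicate 3, edgeR called 0 genes (3449 at an unadjusted p under 0.05), limma-voom 0, with 0 higher and 0 lower (3532 at an unadjusted p under 0.05), and DESeq2 1466, of which 545 were higher. Of the named genes, 78, 80 and 111 lost their call without PBS replicate 1, 2 and 3 and 8, 61 and 78 without syringin replicate 1, 2 and 3, against at most 34 under any other setting on all 6 libraries, and 0 changed sign with a call. With each library left out the number of called lists was between 32 and 39, against 34, and with an estimated correlation it was 0, with fry 15 and with rank-based camera 35; the length and GC correction and the ganglion covariate each gave 37. The glucocorticoid response list, not called with all libraries, was between -0.19 without PBS replicate 3 and 0.22 without PBS replicate 1, where it was called in the other direction (adjusted p = 0.0372); the cause was not tested. The 500 most variable genes put 33.9% of the variance on the first component, against 32.1%, and there the first component did not separate the treatments; the second, with 21.9%, did.

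With the replicate number as a replicate block, 2557 genes were called, 1062 higher and 1495 lower, and 37 lists, which gained oligodendrocyte progenitors, endothelial cells and dendritic cells, all higher (adjusted p = 0.0266, 0.0467 and 0.0257), and lost none. Deviations from the group means correlated, across genes, by 0.292, 0.123 and 0.052 between libraries of the same number, and PBS library 3 correlated best with syringin library 2 (0.135), so the numbers are taken to name samples, not to pair them. Counting error weighed most on genes of few counts, by a comparison chosen after the result was seen. Among the 5528 tested genes with the fewest counts (median 24.3) the median standard error was 0.57, and counting error alone gave a median of 18.4% of its square, or 73.4% if 1 fragment adds 4 counts. Among the 5529 with the most counts these were 0.11, 1.89% and 7.54%.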

Other observations

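The enrichment tests, and the tests on the share of cord tissue, a grey matter lesion, blood and lost neuronal RNA, were chosen only after the result was seen. Among the higher genes, 26 of 366 genes annotated to actin binding were found where 7.5 would fall by chance (adjusted p = 5.29e-05, hypergeometric test over 2835 GO terms). Of 15 genes of actin nucleation by the Arp2/3 complex, which starts branched actin filaments, 5 rose (adjusted p = 0.00258). These were the subunits Actr3 (log2 fold change 0.37 ± 0.08), Arpc1b (0.51 ± 0.10), Arpc2 (0.45 ± 0.09) and Arpc5 (0.50 ± 0.10), and Trim27 (0.46 ± 0.09), each with n = 3 in each group and named after its values were seen. Cytokine-mediated signalling held 16 higher genes of 122 (adjusted p = 1.08e-05). In all 61 GO terms were enriched among the higher and 222 among the lower genes, and 6 and 37 of 318 KEGG terms. Neuron projection led the lower GO terms, with 76 of 349 genes (adjusted p = 9.92e-30), and neuroactive ligand-receptor interaction the lower KEGG terms, with 44 of 285 (adjusted p = 7.04e-11). The hypergeometric test takes genes as independent and equally likely to be called. The called share was 0.34% of the 5528 tested genes with the fewest counts and 9.93% of the 5529 with the most. These p-values therefore do not measure the spread between animals. Without PBS library 3, edgeR called 0 genes.

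Avil and Scn11a, 2 members of the sensory ganglion list picked after their values were seen, were higher in PBS library 1 and in syringin libraries 1 and 3 than in the other 3: Avil stood at 35.9, 1.2 and 1.33 CPM in the PBS and 35.2, 1.16 and 14.6 CPM in the syringin libraries, and Scn11a at 19.8, 0.134 and 0.161 CPM in the PBS libraries. Scn11a was at 18.8, 0 and 7.22 CPM in the syringin libraries, where a count of 0 allows up to 3 fragments. A piece of ganglion or root in the dissected tissue may explain these values, and with the ganglion mean as a covariate 2589 genes were called in place of 1108, but the piece taken was not analysed here.

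The lower values of neuronal genes had a median log2 fold change of -0.72 over 88 members of 5 lists. A bias of transcript length and GC content and syringin library 2 are argued against as the whole cause, because the median was -0.58 after correction and -0.61 without that library. A smaller share of cord tissue would lower neuron, astrocyte and oligodendrocyte genes alike. Astrocyte genes went with it, at a median of -0.59 with 7 of 14 fallen, against -0.72 for the neuron list. Oligodendrocyte and myelin genes did not, at a median of 0.11, which is 0.83 above neuron genes (permutation test over genes, p = 6e-05). That p takes genes as independent, so it does not measure the spread between animals. The oligodendrocyte list mean was -0.28, 0.05 and 0.01 in the PBS and -0.07, -0.02 and 0.31 in the syringin libraries. The neuron list mean was 0.48, 0.17 and 0.34 in the PBS and -0.09, -0.71 and -0.20 in the syringin libraries. These means argue against a smaller share of all cord tissue as the whole cause. They do not argue against a smaller share of a part of the cord with neurons and astrocytes. Another level of the cord stays open. Rostral Hox genes lay 0.34 above caudal ones (medians -0.33 over 15 genes and -0.67 over 8 genes). The permutation test over genes gave p = 0.0212, past 0.05, but the gap was under the bound of 0.5 set in advance. That p, too, takes genes as independent and does not measure the spread between animals. Of these genes, 2 rostral and 1 caudal passed an adjusted p of 0.05 in edgeR. A larger grey matter lesion in the pieces taken from treated animals stays open, because only 4 of 6 pairs of libraries of 1 group had the lower neuronal mean with the higher macrophage mean (exact one-sided permutation p = 0.361, 36 arrangements); this replaced a correlation of the same values, which left it open too. An effect of syringin on neuronal genes or on neuron loss is a further open hypothesis, and no value here separates it from these.

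The higher values of macrophage, inflammatory and cell cycle genes had a median of 0.64 over 87 members of 4 lists. The median was 0.55 without syringin library 2, which argues against that library alone. Infiltrating macrophage genes lay 1.46 above astrocyte genes (permutation test over genes, p = 9e-05). The list medians had already shown that gap, and that p does not measure the spread between animals. The astrocyte list mean was 0.23, 0.27 and 0.44 in the PBS and -0.51, -0.22 and -0.22 in the syringin libraries. This fall argues against a loss of neuronal RNA that raises every other cell type alike, astrocytes included. It does not argue against a loss of neuronal and astrocyte RNA together. More blood in the tissue stays open, since the erythroid median was -0.22 with members on both sides of 0. A stronger myeloid infiltration, or more myeloid tissue in the pieces taken from treated animals, may each give these values, and the design cannot tell them apart.

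The higher values of cytosolic ribosomal protein genes had a median of 0.30, which was 0.29 after the length and GC correction, so that bias is argued against as the whole cause. Reads shared with pseudogenes and a change in cell makeup were not tested and stay open.

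Of the 10 splits of the 6 libraries into 3 and 3, only 1, the real split, gave as many as 1108 changed genes, and the highest other gave 5. That split set PBS library 1 with syringin libraries 1 and 3, the libraries with ganglion transcripts. With 10 splits the share cannot go under 0.05. Every other split put both treatments in each set of 3. A difference between the groups, from any cause, then widens the spread within the sets and lowers the calls. The gap between 1108 and 5 therefore shows neither the cause nor the size of a difference.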
